A study of Homo sapiens with 12 samples.

How the data were processed

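Whole blood of each participant was placed in 3 tubes with 100 µl of sterile water (Control), heat-killed Escherichia coli (HKEC) or heat-killed Staphylococcus aureus (HKSA) and kept for 6 h at 37 °C, per the labels' protocols. The RNA was collected in PAXgene tubes, depleted of globin and ribosomal RNA and sequenced as paired reads of 150 bases on an Illumina NovaSeq instrument. There were 12 libraries, 4 in each of 3 groups.

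Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5 and aligned to GRCh38 with STAR, and DESeq2 1.34.0 was named without a role. The deposited raw table holds counts per Ensembl gene, which the authors made from those alignments. The counter, the annotation release and the strandedness of the counting are not given in the sources used here. The deposited normalized table holds a signal that equals the raw count divided by 1 factor per library, as found from the ratio of the deposited tables. These factors lay within 0.112% of size factors recomputed from the counts. Of 21297 genes, 21212 matched GENCODE 29 by Ensembl identifier, 19699 of them with the same version, and 85 genes had no name. Coordinates are those of GENCODE 29 on GRCh38. Genes on the Y chromosome, XIST and TSIX (26 in all) were left out of all tests and tables, because the samples come from people.

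Library totals ranged from 12675437 to 17553392 counts. CPM values were computed with library sizes scaled by TMM factors. Genes were tested on the raw counts with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by its quasi-likelihood test, two-sided, with all 12 libraries in 1 fit, group as the only term, and filterByExpr with a minimum count of 10, which kept 18031 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with standard errors (SE), and group means with the SD of the 4 libraries. Each SE was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For a gene with 1 to 3 counts over a whole group, the ratio of CPM is given with a 95% exact binomial interval. With 0 counts, the ratio against 3 assumed counts over the group is given, with the lower limit of that interval as a bound. Intervals and bounds cover counting error only.

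Before the data were examined, 43 gene lists were fixed, and 1079 of their 1156 entries were measured. Of these lists, 41 could be tested, and those of haemoglobin genes and of type I and III interferon genes could not, for want of measured members. The NRF2 target list was tested because the series title names that pathway. Its choice is therefore not independent of the submitters' reading of these libraries. Lists were tested with limma's camera at a preset correlation of 0.01 on log2 CPM, two-sided, with adjustment over the lists of a comparison. Camera with a correlation estimated for each list and limma's fry were run beside it. Fry tests whether the genes of a list move one way on balance, or change in either direction, without comparing them with other genes. The rule for naming genes was also fixed then. For each comparison it took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM, no overlap between the groups, and a gene symbol. It also took up to 4 members of each list by smallest adjusted p (2 per direction where a list went both ways), and any member of the NRF2 lists. Fewer genes than this are named, with preference for calls that held without each library in turn.

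No label says which libraries share a participant, but each run of 3 consecutive library numbers holds 1 library of each group. Libraries of 1 run deviated together from their group means. All 12 correlations were over 0.1, with a mean of 0.555, the highest of 576 assignments (one-sided exact permutation p = 0.00174, next highest mean 0.395). The runs were therefore taken as participants and used as blocks in an alternative fit, whose values are given where they change a call or move a count by over 1.5 times.

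The tests were checked on simulated counts with 200 changed genes per comparison, beside the NRF2 target genes, which were all raised by 1 on the log2 scale. The simulated libraries were drawn independently, without shared participants. For log2 changes of 1, 38% of changed genes were recovered in HKEC against Control, 33% in HKSA against Control and 29% in HKEC against HKSA, and for log2 changes of 2, 88%, 88% and 90%. False calls made up 4.32%, 8.11% and 5.34% of all calls, those of NRF2 target genes included, with 17663, 17654 and 17643 genes run.

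The alternatives were the block, RLE factors, DESeq2 1.42.0, limma-voom, limma-trend on the log2 of the deposited normalized value with pseudocounts of 1 and 0.1, no filter beyond 1 count, a minimum count of 50, the 8 libraries compared alone, totals without haemoglobin and mitochondrial genes, a minimum absolute log2 fold change of 1, and leaving out each library. Overlap between the bacteria was set against 20 simulations of unchanged groups, against independent lists, and against fits with the Control libraries split. Shares of counts were compared by two-sided exact permutation tests, and within blocks by exact sign flips. Differential splicing, variants and allele-specific counts were not analysed here.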

Results

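Human whole blood from each participant was divided into 3 tubes that held sterile water (Control), heat-killed Escherichia coli (HKEC) or heat-killed Staphylococcus aureus (HKSA). The blood was kept at 37 °C for 6 h before its RNA was stabilised, depleted of globin and ribosomal RNA, and sequenced. The series holds 12 libraries, 4 in each group. Total counts of the Control libraries were 14588894, 14556759, 17553392 and 12675437 in replicates 1 to 4. The HKEC libraries had 16805904, 13994225, 17448450 and 14027163 counts, and the HKSA libraries 14005824, 15638974, 17018824 and 13795726. Of the 21297 genes in the deposited tables, 18031 passed the filter on low counts and were tested. A principal component analysis of the 2000 most variable genes placed 59.9% of the variance on a first component that set the 4 Control libraries (at -63.47 to -77.65) apart from the 8 libraries with bacteria (at 25.5 to 46.1).

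**Figure D1:**
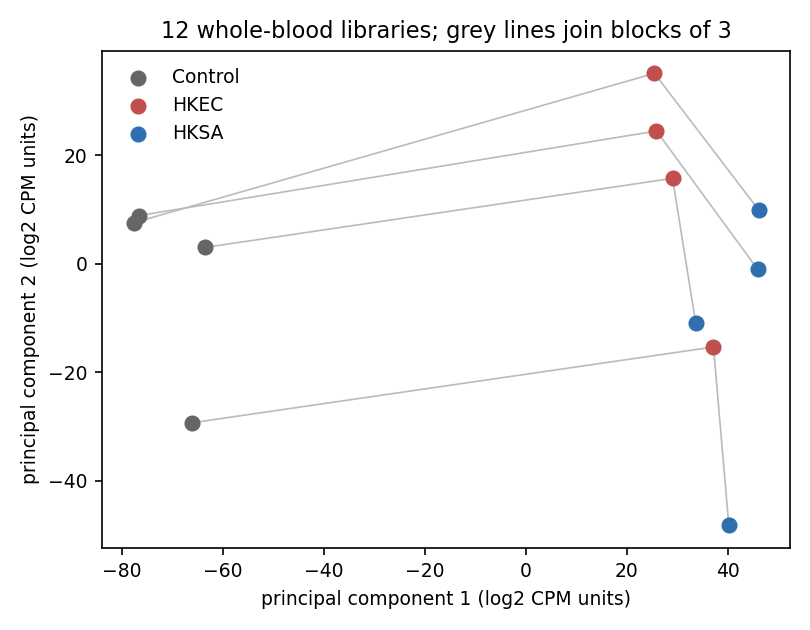
First and second principal components (log2 CPM units) of the 12 libraries, coloured by group; grey lines join the 3 libraries with consecutive library numbers. The first component holds 59.9% and the second 11.4% of the variance, and all 4 Control libraries lie on one side of the first.

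The comparison of HKEC with Control asks how whole blood responded to a Gram-negative bacterium. Blood with heat-killed E. coli carried far more transcripts of secreted inflammatory mediators and of interferon-stimulated genes, and far fewer of several monocyte and neutrophil genes. CSF3, which encodes the granulocyte growth factor G-CSF (ENSG00000108342.12, GRCh38 chromosome 17, 40015361 to 40017813), averaged 271 ± 48.8 CPM (SD, n = 4) with HKEC and 0.0883 ± 0.0765 CPM in Control. IL6, a cytokine of the acute phase response, averaged 550 ± 185 CPM against 1.16 ± 1.299 CPM (SD, n = 4 each), with 3.11 CPM in Control replicate 1 and 0.419 to 0.598 CPM in the other Control libraries. IL1B, a cytokine released through the inflammasome, averaged 7772 ± 2480 CPM against 394 ± 147 CPM. Among the falls, FN1, which encodes the matrix protein fibronectin, averaged 0.258 ± 0.0527 CPM against 41.1 ± 30.6 CPM, and CXCR2, a chemokine receptor of neutrophils, 6.26 ± 1.93 CPM against 204 ± 92.1 CPM.

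With edgeR's quasi-likelihood test, 4249 of 18031 genes differed at an adjusted p under 0.05, 2173 of them higher and 2076 lower with HKEC. With blocks of 3 libraries taken as participants the count was 7077, which included all 4249. The 4 libraries of one group lay wholly above or below the 4 of the other for 24.5% of genes tested, where chance gives 2.86%. The largest rises in log2 fold change were those of CSF3 (11.41 ± 0.57, SE), the interleukin-1 family cytokine IL36G, the receptor gene MAS1, the interleukin-12 subunit IL12B, the cytochrome CYP3A5, IL6 (8.85 ± 0.67), the collagenase MMP1 and ACOD1 (7.89 ± 0.79), which makes the metabolite itaconate. Control counts were 3 or fewer over the whole group for IL36G, MAS1, IL12B, CYP3A5 and MMP1. Ratios of CPM with their 95% counting intervals were 3860 (692 to 152000) for IL36G, 1110 (308 to 9210) for IL12B, 1130 (203 to 44800) for CYP3A5 and 374 (103 to 3090) for MMP1. MAS1, with no Control count, was 304-fold higher when 3 counts are assumed over the Control group, and its lower 95% counting bound was 247-fold. The largest falls were those of FN1 (-7.29 ± 0.68), the macrophage complement receptor VSIG4 (-7.18 ± 0.69), the long non-coding RNA LINC02289 (-7.04 ± 0.66), the lectin CLEC10A (-6.45 ± 0.56), the eosinophil-attracting chemokine CCL24 (-5.50 ± 0.47), the formyl peptide receptor FPR3 (-5.27 ± 0.53), CXCR2 (-5.03 ± 0.46) and the matrix protein gene TGFBI (-4.92 ± 0.37). The adjusted p of these 16 genes ranged from 5.62e-07 to 6.91e-04. Single libraries moved several of these changes by over 1.5 times. On the log2 scale IL6 reached 10.1 without Control replicate 1, ACOD1 fell to 7.08 without HKEC replicate 3, and MAS1 and IL12B were at 9.93 and 8.38 without HKEC replicate 3. IL36G and CYP3A5 reached 12.8 and 11.1 without Control replicate 2. Counts over all 4 Control libraries were 0 for MAS1, 2 for IL12B, and 1 each for IL36G and CYP3A5. The fitted sizes of these genes are therefore not measured changes, and only the bound and intervals above hold. VSIG4 and CCL24 were at -8.50 and -6.53 without HKEC replicate 4, and CLEC10A was at -7.46 without HKEC replicate 2.

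Cytokine and chemokine genes rose together. Of 28 pro-inflammatory cytokine genes measured, 23 rose and 1 fell (24 and 1 adjusted over the list alone), with a median log2 fold change of 2.31. The list's adjusted p was 2.69e-14 by camera, and 0.171 with an estimated correlation. Lists other than that of NRF2 targets were tested without each library in turn after the data were seen, and this list's median was 1.66 without HKEC replicate 3. IL1B rose 19.7-fold (edgeR adjusted p = 2.52e-05), and the interleukin-18 gene IL18 fell 5.38-fold (edgeR adjusted p = 2.24e-04). Of 25 chemokine genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 3.28, adjusted p = 2.17e-08), which camera also called with an estimated correlation (adjusted p = 0.0169) but not with the blocks added to it (adjusted p = 0.232). CCL20, which attracts dendritic cells and lymphocytes, rose 44.2-fold, and the monocyte chemokine CCL7 rose 19.4-fold. Among 33 anti-inflammatory cytokine and signal inhibitor genes, 18 rose and 4 fell (20 and 4 adjusted over the list alone; adjusted p = 1.18e-08, and adjusted p = 0.361 with an estimated correlation). The signalling inhibitor SOCS1 rose 9.43-fold, IL19 rose 67.2-fold and TGFB1, which encodes transforming growth factor beta, fell 2.005-fold.

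Of 50 interferon-stimulated genes, 43 rose and 0 fell (47 and 0 adjusted over the list alone; 47 and 1 with the blocks), with a median log2 fold change of 2.62, or 1.68 without HKEC replicate 3. The list's adjusted p was 1.95e-15, and 0.583 with an estimated correlation. Of the 35 splits of these 8 libraries into groups of 4, 8 gave as small a camera p. HERC6, a member of a ubiquitin ligase family, rose 9.81-fold, the transcription factor IRF7 rose 6.78-fold and the helicase gene HELZ2 rose 6.67-fold (2.74 on the log2 scale, and 2.15 without HKEC replicate 3). In the list of interferon-gamma and guanylate-binding protein genes, 9 of 27 rose and 0 fell (13 and 1 adjusted over the list alone; 16 and 1 with the blocks; adjusted p = 8.59e-04, and adjusted p = 0.925 with an estimated correlation). IDO1, which degrades tryptophan, rose 17.2-fold and the transcription factor BATF2 rose 21.9-fold. On the log2 scale these were 4.10 and 4.45, against 3.10 and 3.75 without HKEC replicate 3, and BATF2 reached 5.07 without Control replicate 2.

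Coagulation and matrix remodelling genes rose in 15 of 27 cases and fell in 5 (15 and 5 adjusted over the list alone; adjusted p = 6.65e-05, and adjusted p = 0.347 with an estimated correlation). SERPINB2, an inhibitor of plasminogen activation, rose 115-fold, and F3, which encodes tissue factor, rose 15.7-fold. Costimulation genes rose in 17 of 27 cases and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 1.76e-06, and adjusted p = 0.361 with an estimated correlation). SLAMF1 rose 27.9-fold and IL2RA, the interleukin-2 receptor alpha chain, 37.4-fold, while CD86, a costimulatory ligand of antigen-presenting cells, fell 7.25-fold. Of 36 pattern recognition receptor genes, 5 rose and 12 fell (6 and 15 adjusted over the list alone; 10 and 20 with the blocks; adjusted p = 0.0194, and adjusted p = 0.921 with an estimated correlation). The scavenger receptor SCARF1 rose 3.65-fold and CD36 fell 7.97-fold. Cytosolic ribosomal protein genes (adjusted p = 7.88e-03, and adjusted p = 0.995 with an estimated correlation) and mitochondrially encoded transcripts (adjusted p = 0.0467, and adjusted p = 0.952 with an estimated correlation) were called higher as lists, although 0 of 71 and 0 of 13 members passed the edgeR test alone (8 and 5 with the blocks). The ribosomal list was not called by camera without HKEC replicate 4 (adjusted p = 0.208), nor pattern recognition without HKEC replicate 1 (adjusted p = 0.0974). Camera did not call the mitochondrial list without Control replicate 3 (adjusted p = 0.148), HKEC replicates 2 or 3 (0.167 and 0.0793) or HKSA replicate 3 (0.0502).

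Markers of monocytes and neutrophils fell, while lists of T cell, B cell, NK cell, platelet and erythroid markers were not called. Of 20 monocyte markers, 0 rose and 10 fell (0 and 11 adjusted over the list alone; 0 and 16 with the blocks; median log2 fold change -1.40, adjusted p = 9.14e-08, and adjusted p = 0.361 with an estimated correlation). MPEG1, a pore-forming protein of phagocytes, fell 11.5-fold, the lipid-presenting molecule CD1D fell 19.2-fold and VCAN, a matrix proteoglycan made by monocytes, fell 14.7-fold. Of 19 neutrophil markers, 0 rose and 13 fell (0 and 14 adjusted over the list alone; median -2.13, adjusted p = 3.52e-07, and adjusted p = 0.529 with an estimated correlation). CXCR1 fell 15.9-fold and BTNL8 fell 4.36-fold. The NADPH oxidase and NADPH source genes rose in 1 of 19 cases and fell in 7 (2 and 8 adjusted over the list alone; 3 and 11 with the blocks; adjusted p = 0.0194, and adjusted p = 0.529 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, rose 3.07-fold. Of the 35 splits, 21 gave as small a camera p as the real one for ribosomal protein genes, 17 for interferon-gamma genes, 16 for pattern recognition, 14 for mitochondrially encoded transcripts and 5 for the NADPH list. Costimulation genes, monocyte markers and neutrophil markers had 3 and anti-inflammatory genes 2, while pro-inflammatory cytokines, chemokines and coagulation had only the real split.

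NRF2 target genes went both ways with HKEC. NRF2, encoded by NFE2L2, is the transcription factor that drives antioxidant and detoxification genes. Of 40 target genes measured, 10 rose and 8 fell (10 and 9 adjusted over the list alone; 11 and 13 with the blocks), with a median log2 fold change of 0.24 and a mean of 0.02. The list was not called by limma's camera (adjusted p = 0.972), while limma's fry called it for change in either direction (adjusted p = 1.92e-09). TXN, which encodes thioredoxin, rose 6.41-fold, the cystine transporter gene SLC7A11 rose 5.84-fold and GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, rose 3.55-fold (edgeR adjusted p = 1.60e-04, 3.45e-04 and 3.95e-04). TKT, which encodes transketolase, fell 4.36-fold, and the quinone reductase NQO2 fell 2.97-fold. NFE2L2 itself averaged 340 ± 98.7 CPM against 191 ± 36.3 CPM (SD, n = 4 each; edgeR adjusted p = 0.0277), a call that was lost without any 1 of 6 libraries (Control replicates 1, 2 and 4 and HKEC replicates 2, 3 and 4; adjusted p up to 0.0821). Of 25 NRF2 pathway regulators, 5 rose and 2 fell (7 and 2 adjusted over the list alone; 9 and 4 with the blocks), among them the small Maf proteins MAFF (4.90-fold higher) and MAFG (2.34-fold higher) and the nuclear receptor RXRA (2.33-fold lower). The regulator list was not called by limma's camera (adjusted p = 0.165).

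The comparison of HKSA with Control asks the same of a Gram-positive bacterium. Blood with heat-killed S. aureus also carried many more transcripts of cytokines and chemokines and fewer of monocyte and neutrophil genes, and several NRF2 target genes were higher. GCLM (ENSG00000023909.9, GRCh38 chromosome 1, 93885205 to 93909456) averaged 341 ± 130 CPM with HKSA and 12.4 ± 2.23 CPM in Control (SD, n = 4 each). TXNRD1, which encodes thioredoxin reductase, averaged 852 ± 250.1 CPM against 80.6 ± 15.6 CPM, and SLC7A11 averaged 629 ± 166 CPM against 31.8 ± 11.7 CPM. CSF3 averaged 132 ± 63.3 CPM against 0.0883 ± 0.0765 CPM, and IL6 averaged 328 ± 103 CPM against 1.16 ± 1.299 CPM (3.11 CPM in Control replicate 1). VCAN averaged 13.1 ± 7.36 CPM against 2070.3 ± 638 CPM.

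With edgeR's quasi-likelihood test, 4884 of 18031 genes differed, 2322 higher and 2562 lower with HKSA, and 7825 with the blocks, which included all 4884. The groups did not overlap for 27.7% of genes, where chance gives 2.86%. The largest rises were those of IL36G, CSF3 (10.37 ± 0.56 on the log2 scale, SE), MAS1, IL12B, MMP1, MTCO1P4, IL6 (8.11 ± 0.65) and ROR1-AS1. Ratios of CPM with their 95% counting intervals were 3240 (582 to 128000) for IL36G, 1540 (426 to 12700) for IL12B, 604 (167 to 5000) for MMP1, 544 (150 to 4500) for MTCO1P4 and 309 (105 to 1500) for ROR1-AS1. MAS1 was 234-fold higher with 3 counts assumed over the Control group, and its lower 95% counting bound was 190-fold. MTCO1P4 is a nuclear pseudogene of a mitochondrial gene and ROR1-AS1 lies antisense to ROR1. Their counts are uncertain because near-identical or opposite-strand sequence could share reads and the strandedness of the counting is not given in the sources used here. The largest falls were those of VSIG4, with a CPM ratio of 607 (109 to 24000) from 1 count in HKSA, and FN1 (-7.47 ± 0.69), VCAN (-7.30 ± 0.58), LINC02289 (-6.52 ± 0.63), FPR3 (-6.22 ± 0.57), the receptor gene SIRPB2 (-6.16 ± 1.07), the lysosomal GTPase RAB7B (-5.81 ± 0.76) and the protease CORIN (-5.71 ± 1.11). The adjusted p of these 16 genes ranged from 5.24e-07 to 2.11e-03. Of these changes, IL6 reached 9.31 without Control replicate 1, IL36G 12.6 without Control replicate 2, and MTCO1P4 and ROR1-AS1 11 and 8.91 without Control replicate 3, where CORIN was at -4.81. MAS1 was at 9.67 without HKSA replicate 3, VSIG4 at -10.4 without HKSA replicate 1 and SIRPB2 at -6.92 without HKSA replicate 2. Counts over the whole Control group were 0 for MAS1, 1 for IL36G, 2 for MTCO1P4 and 3 for ROR1-AS1, and VSIG4 had 1 count over the HKSA group. The fitted sizes of these 5 genes are therefore not measured changes, and only the bound and intervals above hold.

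Of the 40 NRF2 target genes, 17 rose and 6 fell with HKSA (22 and 8 adjusted over the list alone), with a median log2 fold change of 0.72. The list's adjusted p was 1.01e-03 by camera, and 0.543 with an estimated correlation. A camera p as small came from 2 of the 35 splits of these 8 libraries. GCLM rose 27.4-fold, TXN 24.7-fold, SLC7A11 19.8-fold and TXNRD1 10.6-fold, each with an adjusted p of 1.34e-05 or less. OSGIN1, an oxidative stress-induced growth inhibitor, rose 13.5-fold and GCLC, the catalytic partner of GCLM, rose 8.25-fold. NQO1, a quinone reductase, rose 14.6-fold from 0.414 ± 0.286 CPM (SD, n = 4). NQO2 fell 2.48-fold and the retinaldehyde dehydrogenase ALDH1A1 fell 11.2-fold. Without the members that other fixed lists also hold, 16 genes were left and limma's camera did not call the list (adjusted p = 0.189). NFE2L2 averaged 440 ± 99.8 CPM against 191 ± 36.3 CPM (edgeR adjusted p = 3.19e-03), and KEAP1, which marks NRF2 for degradation, rose 2.09-fold (adjusted p = 5.92e-04). Of 25 regulators, 10 rose and 2 fell (10 and 2 adjusted over the list alone; 11 and 4 with the blocks), and limma's camera did not call the list (adjusted p = 0.0526). It did without Control replicates 2 or 3 (adjusted p = 0.0328 and 0.0428), HKEC replicates 1 or 3 (0.0478 and 0.0424) or HKSA replicates 1 or 3 (0.0163 and 0.0463).

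Of 28 pro-inflammatory cytokine genes, 19 rose and 1 fell with HKSA (21 and 1 adjusted over the list alone; 23 and 2 with the blocks; median log2 fold change 2.67, adjusted p = 2.78e-12, and adjusted p = 0.181 with an estimated correlation). Of 25 chemokine genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone; 18 and 2 with the blocks; adjusted p = 4.91e-06, and adjusted p = 0.061 with an estimated correlation), with CCL20 42.5-fold higher and CCL24 23.8-fold lower. Among 33 anti-inflammatory cytokine and signal inhibitor genes, 17 rose and 3 fell (17 and 5 adjusted over the list alone; 18 and 8 with the blocks; adjusted p = 8.45e-05, and adjusted p = 0.58 with an estimated correlation). IL24, an interleukin-10 family cytokine, rose by 7.61 ± 0.60 on the log2 scale (SE), and SOCS2 rose 7.44-fold. Of 50 interferon-stimulated genes, 17 rose and 1 fell (25 and 1 adjusted over the list alone; median 1.53, adjusted p = 3.02e-08, and adjusted p = 0.698 with an estimated correlation), and with the blocks 40 rose and 3 fell. For this list 7 of the 35 splits gave as small a camera p. HERC6 rose 6.95-fold and IRF7 3.71-fold. Coagulation and matrix genes rose in 13 of 27 cases and fell in 5 (13 and 5 adjusted over the list alone; adjusted p = 4.26e-03, and adjusted p = 0.543 with an estimated correlation). Costimulation genes rose in 14 of 27 cases and fell in 1 (16 and 1 adjusted over the list alone; 18 and 3 with the blocks; adjusted p = 5.15e-05, and adjusted p = 0.543 with an estimated correlation).

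Of 20 monocyte markers, 1 rose and 18 fell with HKSA (1 and 19 adjusted over the list alone; median -2.48, adjusted p = 5.12e-12, and adjusted p = 0.181 with an estimated correlation). CSF1R, the receptor for macrophage colony-stimulating factor, fell 29.9-fold, and the lectin CLEC12A rose 2.92-fold. Of 19 neutrophil markers, 0 rose and 16 fell (0 and 16 adjusted over the list alone; median -2.01, adjusted p = 1.42e-07, and adjusted p = 0.547 with an estimated correlation), with CEACAM3 24.1-fold lower. Pattern recognition receptor genes rose in 2 of 36 cases and fell in 16 (2 and 17 adjusted over the list alone; 5 and 22 with the blocks; adjusted p = 8.45e-05, and adjusted p = 0.58 with an estimated correlation), with the Toll-like receptor TLR6 11.4-fold lower. MHC class II genes rose in 1 of 16 cases and fell in 7 (1 and 9 adjusted over the list alone; 1 and 13 with the blocks; adjusted p = 8.08e-03, and adjusted p = 0.58 with an estimated correlation), with HLA-DMA 2.27-fold lower. Of 19 NADPH oxidase and NADPH source genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone; 2 and 9 with the blocks; adjusted p = 0.0282, and adjusted p = 0.58 with an estimated correlation). CYBB, the catalytic subunit of the phagocyte oxidase, fell 11.7-fold. Glycolysis and HIF-1 target genes rose in 5 of 35 cases and fell in 14 (5 and 16 adjusted over the list alone; 8 and 19 with the blocks; adjusted p = 0.026, and adjusted p = 0.853 with an estimated correlation). Camera did not call this list without Control replicate 3 or HKSA replicate 1 (adjusted p = 0.105 and 0.116), nor the NADPH list without HKSA replicate 1 (adjusted p = 0.0549). VEGFA, the vascular growth factor, rose 6.54-fold, while PFKFB4 and PDK4, regulators of glucose use, fell 11.8-fold and 16.8-fold (PFKFB4 by -3.56 on the log2 scale, and -2.93 without Control replicate 3).

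Of 71 cytosolic ribosomal protein genes, 30 rose and 0 fell with HKSA (45 and 0 adjusted over the list alone; 54 and 0 with the blocks; median 0.72, adjusted p = 1.54e-07, and adjusted p = 0.812 with an estimated correlation). RPL24 rose 2.28-fold and RPSA 1.81-fold, values that are uncertain because processed pseudogenes of these genes could share reads. Heat shock and unfolded protein response genes rose in 7 of 27 cases and fell in 0 (8 and 2 adjusted over the list alone; 14 and 2 with the blocks; adjusted p = 0.0175, and adjusted p = 0.547 with an estimated correlation), and camera did not call them without Control replicate 4 (adjusted p = 0.0518). PPP1R15A, which restores translation after stress, rose 7.17-fold, and the chaperone DNAJB9 rose 4.04-fold. Of 13 mitochondrially encoded transcripts, 2 rose and 0 fell (4 and 0 adjusted over the list alone; 8 and 0 with the blocks; adjusted p = 4.26e-03, and adjusted p = 0.698 with an estimated correlation), with MT-ND3 1.69-fold higher. For HKSA against Control, 16 of the 35 splits gave as small a camera p for glycolysis genes, 13 for ribosomal protein genes, 10 for mitochondrially encoded transcripts and for MHC class II, 8 for heat shock genes, 7 for the NADPH list and 3 for pattern recognition. Anti-inflammatory, costimulation and neutrophil lists had 2, while pro-inflammatory cytokines, chemokines, coagulation and monocyte markers had only the real split.

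MTCO1P4 lies in a stretch of chromosome 8 whose other annotated transcripts were looked at after its values were seen, and their genes are outside the naming rule. Downstream of ATP6V1C1, a proton pump subunit gene on the same strand (GRCh38 103021063 to 103073051), lie MTND1P5, MTCO1P4, MTCO2P4, LINC01181 and the leukaemia-associated gene BAALC, which ends at 103230305. On the log2 scale BAALC rose by 5.49 with HKEC and 5.79 with HKSA, LINC01181 by 6.99 and 7.78, and MTND1P5 by 5.95 and 7.199. Without Control replicate 4, LINC01181 reached 8.34 and 9.14, and MTND1P5 6.54 with HKEC. Without Control replicate 3 the fitted change of MTCO1P4 with HKEC moved from 7.55 to 9.74. MTCO1P4 and MTCO2P4 had 2 counts each over the Control group, and their CPM ratios with HKEC were 236 (64.9 to 1950) and 44 (11.8 to 369). With HKSA the ratio of MTCO2P4 was 115 (31.5 to 958). ATP6V1C1 rose by 0.66 on the log2 scale with HKEC (edgeR adjusted p = 0.0563, and 0.000434 with the blocks; 0.0224 without HKEC replicate 1 and 0.0266 without HKSA replicate 1) and by 1.41 with HKSA (edgeR adjusted p = 7.06e-04).

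The comparison of HKEC with HKSA asks where the bacteria differed, and the series title names the NRF2 pathway as a point of difference. NRF2 target genes were lower with HKEC than with HKSA, and several transcripts of myeloid cells were higher. GCLM averaged 44.2 ± 4.42 CPM with HKEC and 341 ± 130 CPM with HKSA (SD, n = 4 each), and TXNRD1 178 ± 49.7 CPM against 852 ± 250.1 CPM. TXN averaged 25.6 ± 7.66 CPM with HKEC and 98.7 ± 46.6 CPM with HKSA. In the other direction ACOD1 averaged 353 ± 314 CPM with HKEC and 15.7 ± 7.46 CPM with HKSA, and VCAN 141 ± 74.2 CPM against 13.1 ± 7.36 CPM. ACOD1 stood at 807 CPM in HKEC replicate 3 and at 90.0 to 294 CPM in the other HKEC libraries.

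Of the 40 NRF2 target genes, 0 were higher and 14 lower with HKEC than with HKSA (0 and 21 adjusted over the list alone; 0 and 20 with the blocks). Their median log2 fold change was -0.73. The list's adjusted p was 6.16e-16 by camera, and 0.0216 with an estimated correlation. With the blocks added to the estimated correlation camera did not call it (adjusted p = 0.13). The 8 members GCLM (7.72-fold lower), OSGIN1 (7.195-fold), TXNRD1 (4.78-fold), GCLC (4.87-fold), PIR (4.49-fold), TXN (3.85-fold), GSR (3.29-fold) and MAFG (2.92-fold) kept their calls without each of the 12 libraries in turn. PIR encodes an iron-binding nuclear protein and GSR is glutathione reductase. The other 6 called members were NQO1, SLC7A11, SRXN1, TALDO1, FTL and TRIM16L. Each of these 6 lost its edgeR call without HKSA replicate 4. NQO1 also lost it without HKEC replicates 2 or 3 (adjusted p up to 0.0709), SLC7A11 without HKEC replicates 1 or 2 or HKSA replicate 3 (up to 0.0728), and FTL without HKEC replicates 1, 2 or 4 or HKSA replicate 3 (up to 0.0819). TALDO1 lost it without any 1 of the HKEC libraries or HKSA replicates 2 or 3 (up to 0.0873). SRXN1 kept its call only without Control replicate 1 or HKSA replicate 1 (up to 0.133 otherwise), and TRIM16L only without HKEC replicate 3 or HKSA replicates 1 or 2 (up to 0.152 otherwise). FTL, the ferritin light chain, and TRIM16L are uncertain because pseudogenes or a near-identical copy could share their reads.

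HMOX1, which encodes haem oxygenase 1 (ENSG00000100292.16, GRCh38 chromosome 22, 35380361 to 35394214), averaged 377 ± 190 CPM in Control, 151 ± 79.2 CPM with HKEC and 633 ± 598 CPM with HKSA (SD, n = 4 each). The HKSA mean rests on HKSA replicate 2, at 1516 CPM, while the other HKSA libraries, at 226 to 483 CPM, lay within the Control range of 219 to 629 CPM. Between HKEC and HKSA HMOX1 did not pass the edgeR test (adjusted p = 0.0974) but did with the blocks (adjusted p = 0.0328), and its log2 fold change of -2.07 was -1.17 without HKSA replicate 2. NFE2L2 averaged 340 ± 98.7 CPM with HKEC and 440 ± 99.8 CPM with HKSA (edgeR adjusted p = 0.559, and 0.0486 with the blocks). The blocks also brought the adapter protein SQSTM1, KEAP1 and MAFF past the threshold, each lower with HKEC (edgeR adjusted p = 0.052, 0.052 and 0.0661 without the blocks, and 2.28e-03, 0.0109 and 3.01e-03 with them). Without HKSA replicate 1 edgeR called all 3 (adjusted p = 9.84e-03, 2.99e-03 and 0.0328), and without HKEC replicate 3 it called MAFF (adjusted p = 0.0391). Of 25 regulators 0 were higher and 1 lower (2 and 6 adjusted over the list alone; 3 and 7 with the blocks). The 1 lower was MAFG, which is also among the called NRF2 targets above. Limma's camera did not call the regulator list (adjusted p = 0.0566), although it did without HKEC replicate 2 (adjusted p = 0.017) or HKSA replicates 1 or 3 (4.84e-03 and 0.0404). Of 31 glutathione genes, 0 were higher and 4 lower with HKEC (1 and 4 adjusted over the list alone; 2 and 6 with the blocks; adjusted p = 0.0111, and adjusted p = 0.448 with an estimated correlation). The 4 lower genes were GCLC, GCLM, GSR and SLC7A11, which are also among the NRF2 targets called lower above. The glutathione list was not tested without them.

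**Figure D2:**
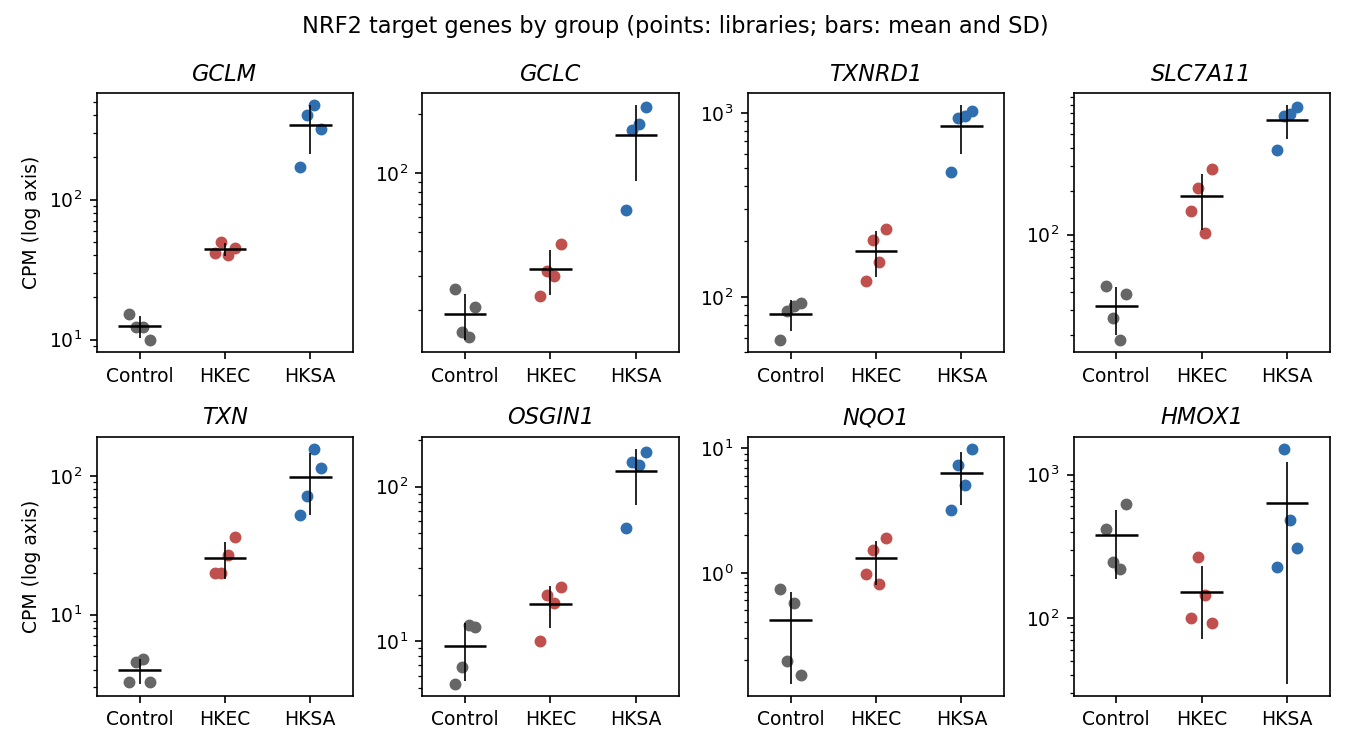
Levels of 8 NRF2 target genes in CPM on log axes, with 1 point per library, and the mean and SD of the 4 libraries of each group. GCLM averaged 12.4 CPM in Control, 44.2 CPM with HKEC and 341 CPM with HKSA, and HMOX1 stood at 1516 CPM in HKSA replicate 2 and at 226 to 483 CPM in the other HKSA libraries.

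Across all genes, edgeR's quasi-likelihood test called 454 of 18031 genes between HKEC and HKSA, 209 higher and 245 lower with HKEC, and 2441 with the blocks, 1351 higher and 1090 lower, which included all 454. The side with more calls depended on single libraries, with 292 higher and 157 lower without HKEC replicate 1, 263 and 172 without HKSA replicate 2, and 118 and 382 without HKSA replicate 1. The groups did not overlap for 7.6% of genes, where chance gives 2.86%. The count fell to 183 without HKEC replicate 2, 288 without HKEC replicate 4, 238 (83 higher and 155 lower) without HKSA replicate 3 and 180 without HKSA replicate 4. The largest rises with HKEC were those of SIGLEC1, a sialic acid receptor of monocytes and macrophages (5.31 ± 1.19 on the log2 scale, SE), ACOD1 (4.49 ± 0.66), CD276, which encodes B7-H3 (3.91 ± 0.59), VCAN (3.43 ± 0.49), PTGES, a prostaglandin E synthase (3.40 ± 0.61), and FAM124A (3.25 ± 0.49). SIGLEC1 averaged 40.2 ± 62.0 CPM with HKEC (133 CPM in HKEC replicate 3, and 4.40 to 12.3 CPM in the others) and 1.01 ± 0.816 CPM with HKSA (2.19 CPM in HKSA replicate 2, and 0.301 to 0.818 CPM in the others), and its adjusted p of 0.0356 rose to as much as 0.122 without any 1 of 8 libraries (Control replicates 2 and 4, HKEC replicates 2 and 3 and the 4 HKSA libraries). Its log2 fold change was 3.19 without HKEC replicate 3, below that of the 5 genes after it as given above, and 5.98 without HKSA replicate 2. ACOD1 was at 3.68 without HKEC replicate 3, and PTGES at 4.10 without HKSA replicate 2. The largest falls were those of IL6R-AS1 (-4.33 ± 0.48), LINC00595 (-3.67 ± 0.34), LINC01262 (-3.29 ± 0.76), CSF2, which encodes the growth factor GM-CSF (-3.20 ± 0.55), XIRP1 (-3.06 ± 0.44), GCLM (-2.95 ± 0.27), DPYSL3 (-2.93 ± 0.48) and the lactate receptor HCAR1 (-2.86 ± 0.47). LINC01262, with an adjusted p of 0.0406, kept its call only without HKEC replicate 4, HKSA replicate 1 or HKSA replicate 3 (adjusted p up to 0.14 otherwise), and its log2 fold change was -4.08 without HKEC replicate 4 and -2.22 without HKSA replicate 4. CSF2 was at -2.60 without HKSA replicate 3. IL6R-AS1 overlaps the interleukin-6 receptor gene IL6R on the other strand of chromosome 1, so reads of these genes cannot be told apart without strand. IL6R was also lower with HKEC (edgeR adjusted p = 0.0315), a call lost in 6 of 12 fits without 1 library. Its log2 fold change ran from -1.86 to -1.47 over those 12 fits.

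Several immune lists were called higher with HKEC than with HKSA, although few of their members passed the edgeR test alone. Beside the NRF2 list, 16 lists were called with these 8 libraries alone, and 12 of their 35 splits called as many (22 of 35 for HKEC and 16 of 35 for HKSA against Control). Taken list by list, as small a camera p came from 20 splits for interferon-stimulated genes, among them all 8 that part the blocks, and from 18 for ribosomal protein genes. It came from 13 for MHC class I and for anti-inflammatory cytokine genes, 12 for receptors, 11 for NF-kB signalling and for pattern recognition, 10 for interferon-gamma genes and 9 for inflammasome and for complement genes. Glycolysis and glutathione genes had 3 such splits and itaconate metabolism 2, while monocyte markers, metallothioneins, prostanoid synthesis and NRF2 targets had only the real split. Monocyte markers were higher in 3 of 20 cases and lower in 1 (11 and 1 adjusted over the list alone; 13 and 1 with the blocks; median 1.16, adjusted p = 2.41e-06, and adjusted p = 0.448 with an estimated correlation). MS4A7 was 3.82-fold higher, and CLEC12A was 4.12-fold lower. Metallothionein and zinc transport genes were higher in 1 of 9 cases (5 adjusted over the list alone; 6 with the blocks; adjusted p = 1.20e-05), which camera also called with an estimated correlation (adjusted p = 0.0216) but not with the blocks added to it (adjusted p = 0.13). SLC39A8, a zinc importer, was 3.33-fold higher with HKEC. Interferon-stimulated genes were higher in 1 of 50 cases (1 adjusted over the list alone; 3 with the blocks; median 0.98, adjusted p = 2.51e-05, and adjusted p = 0.74 with an estimated correlation). This list rested on HKEC replicate 3, without which its median was 0.162 and camera did not call it (adjusted p = 0.286). Interferon-gamma and guanylate-binding protein genes were higher in 2 of 27 cases (3 adjusted over the list alone; 12 with the blocks; adjusted p = 1.23e-07, and adjusted p = 0.663 with an estimated correlation), with a median of 1.08 that fell to 0.474 without HKEC replicate 3 (camera adjusted p = 3.67e-04). Anti-inflammatory cytokine genes were higher in 2 of 33 cases and lower in 1 (6 and 1 adjusted over the list alone; 11 and 1 with the blocks; adjusted p = 4.71e-03, and adjusted p = 0.663 with an estimated correlation). Camera did not call that list without HKEC replicate 3 or HKSA replicate 1 (adjusted p = 0.134 and 0.141). Of 28 pro-inflammatory cytokine genes 1 was higher and 2 lower, and camera did not call their list (adjusted p = 0.629). The higher one was the cytokine subunit EBI3 (2.71-fold). Pattern recognition receptor genes were higher in 4 of 36 cases (5 adjusted over the list alone; 8 higher and 1 lower with the blocks; adjusted p = 1.91e-03, and adjusted p = 0.663 with an estimated correlation), with the formyl peptide receptor FPR2 5.20-fold higher, and were not called by camera without HKSA replicate 1 (adjusted p = 0.0748).

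Some metabolic lists were also called higher with HKEC, while cholesterol and respiratory chain genes were not called. Glutathione genes were called lower, and the 4 members that passed the edgeR test were also NRF2 targets. Glycolysis and HIF-1 target genes were higher in 2 of 35 cases (7 adjusted over the list alone; 20 higher and 2 lower with the blocks; adjusted p = 7.93e-07, and adjusted p = 0.633 with an estimated correlation). Itaconate, tryptophan and arginine metabolism genes were higher in 3 of 14 cases (5 adjusted over the list alone; 5 with the blocks; adjusted p = 1.76e-03, and adjusted p = 0.448 with an estimated correlation), and prostanoid and leukotriene genes in 2 of 20 cases (4 adjusted over the list alone; 6 higher and 1 lower with the blocks; adjusted p = 0.0111, and adjusted p = 0.411 with an estimated correlation). Complement genes were higher in 3 of 22 cases (3 adjusted over the list alone; 7 higher and 2 lower with the blocks; adjusted p = 0.0289, and adjusted p = 0.663 with an estimated correlation), with the complement factor CFB 11.7-fold higher. Camera did not call complement without HKEC replicates 2 or 4 or HKSA replicate 1 (adjusted p = 0.127, 0.0535 and 0.208). Ribosomal protein genes were called lower with HKEC as a list (adjusted p = 4.54e-06, and adjusted p = 0.74 with an estimated correlation), although 0 of 71 members passed the edgeR test alone (2 lower with the blocks). Also called higher were the lists of chemokine and cytokine receptors, NF-kB and Toll-like receptor signalling, inflammasome genes and MHC class I genes, with camera adjusted p from 0.0117 to 0.0165 and 0.663 for each with an estimated correlation. Of the 39 receptor genes 1 was higher and 1 lower (2 and 1 adjusted over the list alone; 15 and 4 with the blocks). Of 34 NF-kB and signalling genes 0 passed (1 higher adjusted over the list alone; 7 higher and 1 lower with the blocks). Of 25 inflammasome genes 1 was higher (4 adjusted over the list alone; 7 higher and 1 lower with the blocks), and of 21 MHC class I genes 0 passed (0 adjusted over the list alone; 3 higher with the blocks). All 4 of these list calls were lost without single libraries. Camera did not call receptors without HKSA replicate 1 (adjusted p = 0.168), NF-kB signalling without HKEC replicates 2 or 3 or HKSA replicate 1 (0.0525, 0.0918 and 0.255), inflammasome genes without HKEC replicate 3 or HKSA replicate 1 (0.178 and 0.0889), or MHC class I without HKEC replicate 3 (0.297).

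**Figure D3:**
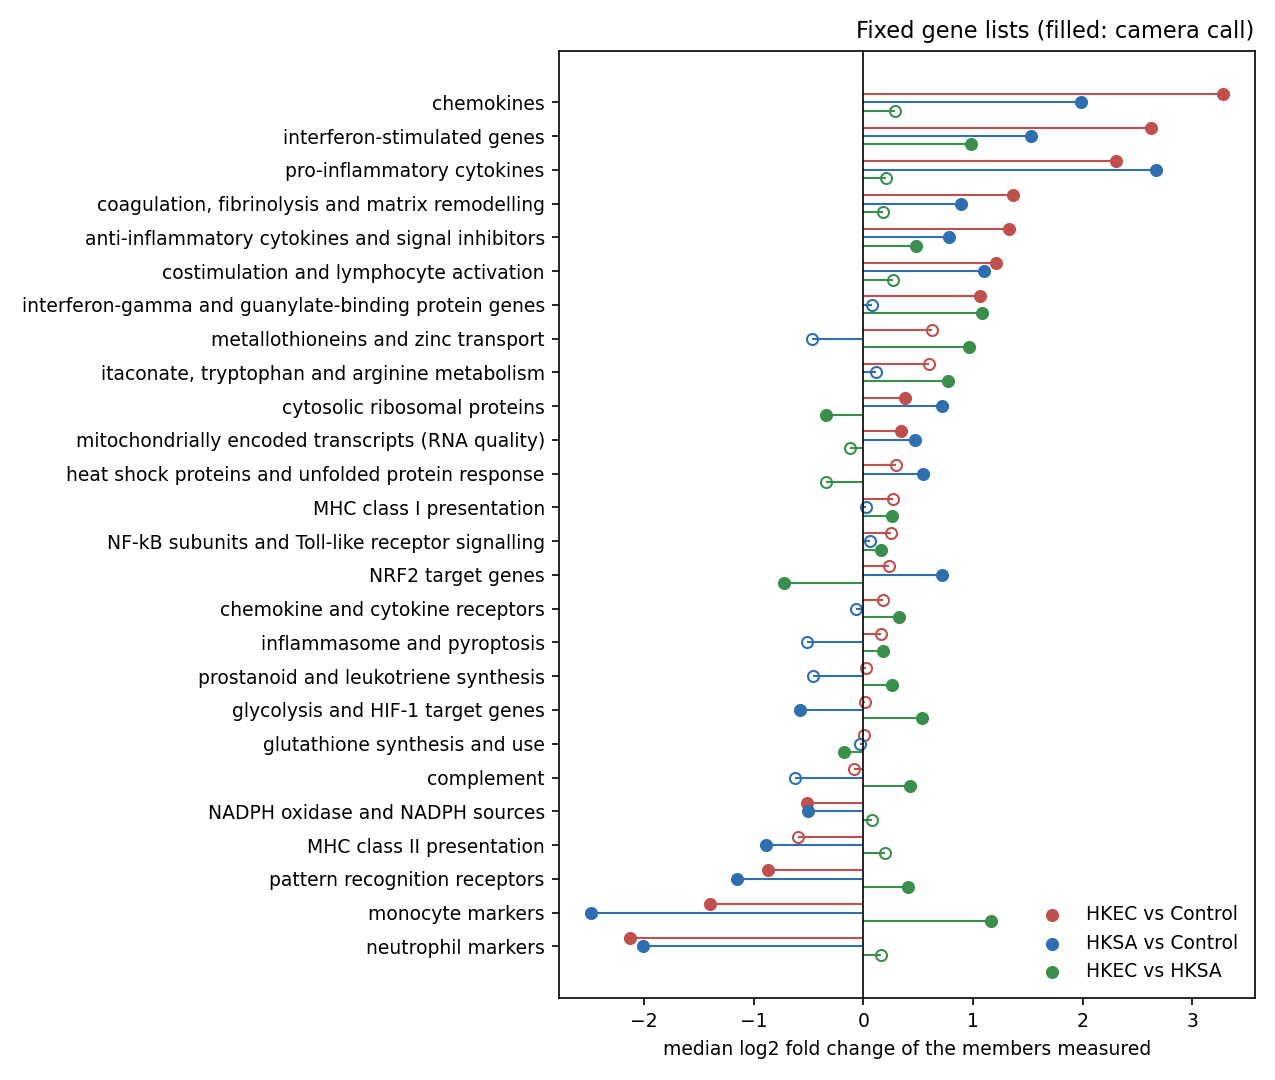
Median log2 fold change of the measured members of each fixed list that camera called in at least 1 comparison, with filled points where the list was called with the preset correlation. Chemokines had a median of 3.28 with HKEC and 1.99 with HKSA against Control, and NRF2 target genes had a median of -0.73 between HKEC and HKSA.

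Most genes changed by one bacterium moved the same way with the other. Of the 4249 and 4884 genes called against Control, 1478 were higher with both bacteria, 1699 lower with both and 1 called in opposite directions, 3177 in the same direction. Independent lists of these sizes would share 279.8 and 295.0 genes. In 20 simulations of unchanged groups against 1 shared set of simulated Control libraries, 0 genes were shared on average. That 0 is no baseline for the counts, because few genes can be called where none change. The simulated libraries were drawn independently, without shared participants. With the Control libraries split into 2 and 2, so that each bacterium had its own, 727 to 811 genes were higher and 909 to 1105 lower with both in 6 fits. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 1.056, against 0.074 in the simulations, a difference of 0.982, and Pearson's r was 0.873 against 0.496. Of the 3177 genes, 156 also differed between HKEC and HKSA. Of the 454 genes that differed between the bacteria, 29 were called in neither comparison with Control. With the blocks 5353 genes moved in the same direction with both bacteria.

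The 10 most abundant genes took 10.4 ± 1.06% of counts in Control, 11.2 ± 1.48% with HKEC and 13.2 ± 1.77% with HKSA (SD, n = 4 each). The smallest of 15 two-sided exact permutation p-values was 0.0571, for this share in HKSA against Control (adjusted p = 0.857), and the smallest that 4 against 4 libraries can give is 0.0286. Compared within blocks, a test chosen after the data were seen, this share was higher with HKSA than in Control and than with HKEC in 4 of 4 blocks, by 2.72 ± 2.0 and 1.93 ± 0.698 percentage points (SD, n = 4). Mitochondrially encoded genes took 0.935 ± 0.191%, 1.003 ± 0.173% and 1.10 ± 0.201% of counts in Control, HKEC and HKSA, and were also higher with HKSA than in Control and than with HKEC in 4 of 4 blocks. The share of the gene RN7SL2 was lower with HKEC than with HKSA in 4 of 4 blocks (difference -0.700 ± 0.719 percentage points, SD, n = 4). The exact sign-flip p was 0.125 in each case, the smallest that 4 blocks can give.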

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

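The tests of cell type share, monocyte number, abundant genes, mitochondrial reads and read-through were chosen after the results were seen.

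In 5 of 60 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's criterion, where chance gives about 3, at 1 in 20. IL6, a cytokine, reached 3.11 CPM in Control replicate 1. NFE2L2, which encodes NRF2, was at 291 CPM and TXNRD1, a target of NRF2, at 480.0 CPM in HKSA replicate 1. SIGLEC1, a sialic acid receptor, stood at 17.2 CPM in Control replicate 3 and at 133 CPM in HKEC replicate 3.

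The changes against Control differed between the bacteria for 454 genes and 17 lists, among them the NRF2 target list (camera adjusted p = 6.16e-16), by the direct test of HKEC against HKSA. With an estimated correlation 15 of the 17 list calls were lost, and the NRF2 list's adjusted p was 0.0216 (0.13 with the blocks added). With only the 8 libraries compared, 16 lists beside the NRF2 list were called, and 12 of 35 splits called as many. Chance cannot be excluded for that count of lists.

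NRF2 target genes such as GCLM and TXNRD1 were lower with E. coli than with S. aureus. Whether a cell type had a lower share in the E. coli tubes cannot be decided here. Marker transcripts can change within cells, and no cell counts were used. The most negative median of 9 marker lists was -0.231 (B and plasma cells, SE over genes 0.149). The NRF2 members' median was -0.73 (SE over genes 0.185), so no marker list was as low. A stronger NRF2 response to S. aureus may explain the lower levels. A difference in dose or in timing between the bacteria also stays open and was not tested.

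Many monocyte markers, such as VCAN, fell with both bacteria (10 of 20 with HKEC and 18 of 20 with HKSA, where 1 rose). With an estimated correlation camera did not call the list (adjusted p = 0.361 with HKEC and 0.181 with HKSA). A loss of monocytes that lowered every marker by the same fold is argued against. With HKEC 10 of 20 markers and with HKSA 7 of 20 lay over 2.5 standard errors from the list's median. Log2 fold changes of the 20 markers ran from -6.45 to -0.185 and from -7.30 to 1.55. Markers that other blood cells also make could fall unequally through cell loss alone, so fewer monocytes as the whole cause stays open. A few genes taking most of the counts would give only -0.0445. A loss of monocytes, changed transcription or both may remain, and these were not separated here.

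The transcripts downstream of ATP6V1C1 on chromosome 8, among them BAALC and MTCO1P4, rose with both bacteria. Reads shared with mitochondrial genes are argued against, since the largest log2 fold change of MT-ND1, MT-CO1 and MT-CO2 was 0.512, while the smallest counting bound of a low-count pseudogene was 11.8-fold (MTCO2P4). Read-through from ATP6V1C1 at an unchanged fraction is argued against, since that gene rose by at most 1.41. Changed termination or a start upstream of BAALC may explain it and was not tested.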

How the results depend on the processing

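All alternatives were chosen before the data were examined, except the comparison of library composition within blocks and the tests of lists other than NRF2 targets without each library, which were chosen after seeing the data. The alternatives changed 1 choice at a time, so the block combined with an estimated correlation was not among them. The comparison within blocks could not pass the threshold, since 4 blocks give no exact p under 0.125. No named gene or list that passed the threshold changed direction under any of them. Fry's test for change on balance gave another direction than camera for 4 lists that neither of these tests called, although fry called all 4 for change in either direction (adjusted p of 3.38e-07 or less). These were NRF2 targets in HKEC against Control and thioredoxin, cholesterol and histone genes in HKSA against Control. The balance of calls turned in HKEC against HKSA, from 209 higher and 245 lower to 1351 and 1090 with the block and 512 and 492 with DESeq2. In HKEC against Control it turned from 2173 higher and 2076 lower to 1922 and 2136 without Control replicate 1. It turned there by little with limma-voom, limma-trend at a pseudocount of 1, a minimum count of 50 and without Control replicate 4 or HKEC replicate 3. In HKSA against Control it turned with a minimum change (1578 and 1418). The cause was not tested.

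With the replicate block the counts of changed genes rose to 7077 (HKEC against Control), 7825 (HKSA against Control) and 2441 (HKEC against HKSA), and 5353 genes moved in the same direction with both bacteria. In HKEC against HKSA it also called SQSTM1, KEAP1, NFE2L2, HMOX1, MAFF and MT2A, in HKEC against Control ATP6V1C1, and over the comparisons 8 more lists. These were metallothionein and zinc transport genes (camera adjusted p = 0.0499), NF-kB signalling (0.049) and MHC class II (5.57e-03) in HKEC against Control. In HKSA against Control they were prostanoid synthesis (0.0436) and NK cell markers (0.0133), and in HKEC against HKSA heat shock proteins (0.0413), T cell markers (0.0215) and NK cell markers (0.0401). With an estimated correlation beside the block none of the 8 was called (adjusted p from 0.253 to 0.632). Together with an estimated correlation it ended the 3 list calls that the estimated correlation had left (adjusted p = 0.232 for chemokines in HKEC against Control, and 0.13 for NRF2 targets and metallothioneins in HKEC against HKSA). The block changed no other call of a named gene, nor of a list with the preset correlation. The common dispersion fell from 0.0876 to 0.028 with it.

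A minimum absolute log2 fold change of 1 left 2530 and 2996 genes against Control and 1923 shared ones, by its own construction. HKEC against HKSA gave 219 genes with only the 8 libraries compared, a fit with fewer samples, and 1004 with DESeq2, where the cause was not tested. Apart from these, the block and the fits without 1 library, all settings gave counts within 1.5 times the 454.

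Leaving out 1 library gave 3294 to 4339 genes in HKEC against Control, 3830 to 5044 in HKSA against Control, 180 to 500 in HKEC against HKSA, and 2405 to 3118 shared by both bacteria. The HKEC against HKSA count fell by over 1.5 times without HKEC replicate 2 (183), HKEC replicate 4 (288), HKSA replicate 3 (238) or HKSA replicate 4 (180). The NRF2 target list kept its side of the threshold in each of these fits, with adjusted p from 0.842 to 0.997, 8.68e-05 to 2.10e-03 and 1.20e-18 to 1.52e-12 in the same order. Of the calls, 2829 of 4249 (66.6%), 3376 of 4884 (69.1%) and 161 of 454 (35.5%) were kept without each library in turn, and 0 changed sign. Of the calls of other lists, 10 of 13, 12 of 15 and 8 of 16 were kept without each library in turn, 7, 4 and 10 lists were gained in at least 1 fit, and the calls over the 3 comparisons numbered 41 to 51 against 44.

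With an estimated correlation the NRF2 target list was not called in HKSA against Control (adjusted p = 0.543), nor without the members that other lists hold (adjusted p = 0.189, 16 genes left). Fry called it for change in either direction in HKEC against Control (adjusted p = 1.92e-09). Of the 44 calls of the other lists over the 3 comparisons, an estimated correlation left 2. Fry called 29 for change on balance and 88 for change in either direction. Fry asks another question than camera. The estimated correlations all lay above the preset 0.01, from 0.0122 (metallothioneins) to 0.863 (platelet markers). They were 0.811 for interferon-stimulated genes, 0.802 for ribosomal protein genes and 0.0832 for NRF2 targets. Calls with the preset value thus assume members that vary more independently than these estimates. How much of each loss this accounts for was not tested.

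Among named genes, 1703 values kept their side of the threshold over the leave-one-out fits, 67 lost it and 6 gained it. Calls that held without each library were preferred in naming, so these counts do not measure the stability of calls at large. Of the calls of named genes, 10 were lost with only the 8 libraries compared, 9 and 5 with limma-trend at a pseudocount of 0.1 and 1, 5 with limma-voom, 3 with a minimum change and 1 each with RLE and without the filter. DESeq2 gained 6, a minimum count of 50 gained 2 and the 8 libraries gained 1. The scaling alternatives moved the median log2 fold change of all genes by -0.00749 to 0.00414, and the share of higher calls ranged from 49.4% (limma-voom) to 51.3% (DESeq2) in HKEC against Control, from 46.4% (limma-voom) to 48.9% (DESeq2) in HKSA against Control, and from 44% (RLE) to 51% (DESeq2) in HKEC against HKSA. RLE factors ended 1 list call in HKEC against Control. At this depth a gene with 3 or fewer counts over a group gives only a bound or a wide interval.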

Other observations

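The counts of other splits of the libraries were set up after the results were seen, and the gene lists before.

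Several gene groups were not called as lists without the blocks, which brought T cell markers (adjusted p = 0.0215) and NK cell markers (adjusted p = 0.0401) in HKEC against HKSA and NK cell markers in HKSA against Control (adjusted p = 0.0133) past the threshold. With an estimated correlation beside the blocks these were not called (adjusted p = 0.506, 0.456 and 0.327). T cell markers (camera adjusted p = 0.944, 0.411 and 0.235 in HKEC against Control, HKSA against Control and HKEC against HKSA), B and plasma cell markers (0.954, 0.449 and 0.245), NK cell markers (0.741, 0.281 and 0.367), platelet markers (0.991, 0.662 and 0.36) and erythroid markers (0.677, 0.832 and 0.453) were not called without them. Dendritic cell markers (0.944, 0.523 and 0.373), eosinophil, basophil and mast cell markers (0.288, 0.304 and 0.706) and neutrophil granule protein genes (0.178, 0.214 and 0.994) were not called either. The same held for thioredoxin and peroxiredoxin genes (0.82, 0.832 and 0.373), iron and haem handling (0.991, 0.662 and 0.245), cholesterol genes (0.993, 0.832 and 0.311), AP-1 and immediate early genes (0.309, 0.111 and 0.0648), nuclear-encoded respiratory chain genes (0.741, 0.559 and 0.872) and histone and cell cycle genes (0.892, 0.936 and 0.522).

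Among lists called in other comparisons, glutathione genes (0.889 and 0.191 in HKEC and HKSA against Control), receptors (0.875 and 0.594), inflammasome genes (0.944 and 0.181), complement (0.773 and 0.155), itaconate and tryptophan metabolism (0.0752 and 0.832), MHC class I (0.21 and 0.832), prostanoid synthesis (0.944 and 0.165), NF-kB signalling (0.0592 and 0.617) and metallothioneins (0.0735 and 0.662) were not called by camera against Control. Nor were glycolysis (0.892), heat shock proteins (0.0837) and MHC class II (0.0592) with HKEC, nor interferon-gamma genes with HKSA (0.916). Between HKEC and HKSA, pro-inflammatory cytokines (0.629), chemokines (0.208), costimulation (0.196), coagulation (0.0572), neutrophil markers (0.373), the NADPH list (0.745), mitochondrially encoded transcripts (0.117), MHC class II (0.367) and heat shock proteins (0.196) were not called. Median, mean and camera's direction differed in sign only in lists that camera did not call, such as glutathione genes with HKSA (median -0.03, mean 0.50, camera higher). Fry called that list higher on balance (adjusted p = 2.08e-03).

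Some of these lists were called by camera without 1 library, in fits chosen after the data were seen. In HKEC against Control these were NF-kB signalling without Control replicates 2, 3 or 4, HKEC replicate 1 or HKSA replicate 1 (adjusted p from 5.87e-03 to 0.0483), metallothioneins without Control replicates 3 or 4 or HKEC replicate 1 (0.0404 to 0.0483), itaconate metabolism without Control replicate 3 or HKEC replicates 1 or 4 (0.0313 to 0.0412) and MHC class II without Control replicates 3 or 4 or HKEC replicate 2 (0.0115 to 0.0459). Heat shock proteins were called without Control replicate 3 or HKEC replicate 1 (0.0464 and 0.0412), erythroid markers without Control replicate 3 (0.0197) and granule protein genes without Control replicate 3 or HKEC replicate 2 (0.0354 and 0.0274). In HKSA against Control AP-1 genes were called without Control replicate 3 or HKSA replicate 1 (0.0349 and 0.0176), and NK cell and platelet markers without HKSA replicate 4 (0.0292 and 0.0218). Between HKEC and HKSA, coagulation was called without HKEC replicates 1 or 3 or HKSA replicates 2, 3 or 4 (0.0103 to 0.0404), AP-1 genes without HKEC replicates 2 or 3 or HKSA replicate 1 (7.80e-04 to 0.0244) and neutrophil markers without HKEC replicate 1 or HKSA replicate 3 (0.0246 and 0.0404). Mitochondrially encoded transcripts were called without HKEC replicate 2 or HKSA replicate 4 (7.66e-03 and 0.0296), heat shock proteins without HKEC replicate 3 (0.0307), and platelet markers without HKEC replicate 3 or HKSA replicate 4 (0.0378 and 5.88e-05). T cell markers were called without HKSA replicate 2 (0.0147), B and plasma cell markers without HKEC replicate 2 (0.0164) and NK cell markers without HKSA replicate 4 (0.0107).

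Other splits of the libraries were examined by all 35 splits of the 8 libraries of each comparison. The real split called 3797 genes in HKEC against Control, 4643 in HKSA against Control and 219 in HKEC against HKSA, and the highest other split 10, 8 and 73. Each was reached by 1 of 35 splits. That share would exclude chance only for independent libraries, and the deviations shared within blocks go against independence. Among the 8 splits that part all 4 blocks, which are too few for a share under 0.05, the highest other called 0 genes in each comparison.

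For the NRF2 target list, 1 of 35 splits gave as small a camera p in HKEC against HKSA (2.52e-17, smallest other 1.12e-10). This too would exclude chance only for independent libraries. The 8 splits that part all 4 blocks are too few for a share under 0.05, where 1 of 8 gave as small a p and the smallest other was 2.29e-10, in a split with 0 genes called. In HKSA against Control 2 of 35 did (5.96e-04 against 2.52e-04), and in HKEC against Control 29 of 35 (0.819 against 0.159), so chance cannot be excluded there. Among the 8 splits, 1 gave as small a p in HKSA against Control (smallest other 0.00133).

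For the other lists the real splits called 13, 15 and 16 lists, and 22, 16 and 12 of 35 splits called as many, with highest others of 24, 19 and 26, so chance cannot be excluded for these counts. Among the 8 splits that part all 4 blocks, 4, 3 and 1 called as many.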
